A study of Homo sapiens with 18 samples.

How the data were processed

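RNA-seq was analysed for 18 libraries of MDA-MB231, a human breast cancer cell line of the triple-negative type, which lacks the oestrogen receptor, the progesterone receptor and HER2 amplification. Per the labels' protocols, the cells carried a retroviral construct from which doxycycline (DOX) induces a short hairpin RNA (shRNA). A pair of hairpins targeted TRA2B and one construct served as control. Structures were grown in Matrigel, a basement membrane gel, and collected on day 8, after culture with DOX at 2 µg/ml or with its solvent DMSO. RNA was taken up with a column kit that includes DNase treatment, and libraries were made with a stranded poly(A) mRNA kit and read as paired ends on a HiSeq instrument. The 6 groups hold 3 libraries each and were taken from the construct and treatment given in the labels.

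The deposited values are raw counts of reads per gene, with no normalization. Per the submitters' processing notes, the tools used were Trimmomatic 0.36, STAR 2.5.1b, featureCounts and Subread, and the genome build was GRCh37. Whether the counting used the strand of the reads is not given in the sources used here. Values of genes that overlap another gene or run antisense to one are therefore uncertain. Among the genes named below this holds for RALGPS2-AS1, SAP30-DT, EPC1-AS2, for WTAPP1, which overlaps MMP1, and for TSNAXIP1, which lies next to CENPT. Only gene counts were analysed here, so splice isoforms, which TRA2B regulates, were not analysed here.

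The table holds 60252 gene identifiers, of which 41 are second copies of genes in the pseudoautosomal region. Symbols came from a gene name table for 40412 identifiers and from GENCODE 29 for 423, and 19417 had none. A RefSeq gene table of another build (GRCh38.p14) served only to find which genes neighbour each other, and no coordinates were taken from it. Library totals ran from 42494046 to 76096339 counts. A count of 3 in the shallowest library corresponds to 0.0706 counts-per-million (CPM), and such limits cover counting error only.

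Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes passed edgeR's default filter on low counts by group, which left 21089, and libraries were scaled by trimmed mean of M values (TMM). All 18 libraries entered a single quasi-likelihood fit of the group means, with robust estimates, 12 residual degrees of freedom and a biological coefficient of variation of 0.0884. The DOX effect of a construct is the log2 fold change of its libraries with DOX against those without. Further contrasts of the same fit took the difference of the DOX effects between each TRA2B hairpin and the control, between the mean of both hairpins and the control, and between the hairpins. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 21089 genes. A gene was called at an adjusted p below 0.05. Levels are TMM-scaled CPM unless stated otherwise, given as mean ± SD of 3 libraries, and log2 fold changes are given with their standard error (SE).

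Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 23 lists within each comparison. The lists were the SR and TRA2 family, hnRNPs and other splicing regulators, nonsense-mediated decay factors, proliferation and mitosis, DNA replication and repair, epithelial markers, mesenchymal markers, extracellular matrix and integrins, a breast cancer lung metastasis signature, interferon response, NF-kB and inflammatory cytokines, the integrated stress response with amino acid synthesis, mitochondrially encoded mRNAs, the nuclear respiratory chain with the mitochondrial ribosome, the unfolded protein response, hypoxia and glycolysis, cholesterol and fatty acid synthesis, TGF-beta and YAP targets, the p53 pathway, cytosolic ribosomal proteins, replication-dependent histones, and markers of luminal and basal mammary epithelium and of haematopoietic cells. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The preset correlation makes camera's p-values small when the genes of a list move together in these libraries, so each list was also tested with an estimated correlation. The median, the mean and the direction of the test differed in sign in 22 of 161 list tests, of which 0 were called by camera with the preset correlation. Of the 57 list calls among these tests, 2 held with an estimated correlation, those of NF-kB and inflammatory cytokines and of the unfolded protein response in the mean of both hairpins against the control.

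Genes were named by a fixed rule. It took TRA2B and TRA2A throughout, and for each DOX effect the 8 highest and 8 lowest log2 fold changes among called genes with a symbol, an average log2 CPM of at least 1 and no overlap between the libraries with and without DOX. For genes changed with both hairpins and beyond the control it took 10 in each direction by the smaller of the 2 changes. For the difference between the mean of both hairpins and the control, and for that between the hairpins, it took 5 in each direction, and for each gene list up to 4 members with the smallest adjusted p. The neighbours of MIR30A and the markers of other cells were named outside this rule, and RMRP, MT-RNR1, MALAT1, TERC, H1-4 and TBX18 were chosen after their values were seen. Some results are not reported here.

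The labels give a sequencing lane for each library. Libraries of shRNA2 with the same replicate number shared a lane, with and without DOX, and their deviations from the group means correlated at 0.52, 0.28 and 0.33 over 13535 genes, so these numbers pair the samples. All control libraries without DOX came from lane 7 and all with DOX from lane 8, and the shRNA1 libraries with and without DOX came from different lanes. In those constructs lane and treatment cannot be told apart. No lane held both control libraries and libraries of a TRA2B hairpin. Construct and lane therefore cannot be told apart where levels are compared between them. Replicate libraries of a group differed by more than sampling noise in every pair, with a chi-square per degree of freedom between 5.29 and 133, so none was counted as a repeat of another. The labels do not say that the 3 libraries of a group came from separate cultures, and p-values then measure the spread between these libraries, which may be technical.

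The tests were checked on simulated counts drawn from the real libraries' means over 21089 genes. For the shRNA1 DOX effect, edgeR recovered 44 of 50 genes changed 1.5-fold and all 50 changed 2-fold, 3-fold or 4-fold, with 20 false calls among 247. Of the other calls, 33 fell on the 80 genes of the simulated lists that were changed 1.3-fold. With no change simulated, it called 0 genes for the shRNA2 DOX effect and 1 for the control DOX effect. For the difference between shRNA1 and the control it recovered 32 of 50 genes at 1.5-fold and 48 at 2-fold, and for the difference between the hairpins 25 at 1.5-fold and 47 at 2-fold. Among 20 simulated lists, drawn at 40 genes each, camera called both lists changed 1.3-fold and 0 of the others for the shRNA1 DOX effect. It ran on the 20702 genes that passed the filter on the simulated counts. Simulated counts were drawn independently for each gene, so this check does not cover lists whose genes move together. The alternatives were DESeq2 1.42.0, relative log expression factors, library totals alone, no filter or a stricter filter on low counts, a fit of only the 2 groups compared, a replicate block, a minimum log2 fold change of 1, a limit of 0.01 on the adjusted p, and leaving out each library in turn.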

Results

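Gene-level read counts were analysed for MDA-MB231, a triple-negative human breast cancer cell line of mesenchymal shape, grown as 3D structures in Matrigel for 8 days. The cells carried shRNA1 or shRNA2 against TRA2B, or a control hairpin, each induced by DOX. With and without DOX at 2 µg/ml this gave 6 groups of 3 libraries. Total counts per library were 67780117 to 72879354 in the control without DOX and 72649428 to 76096339 with DOX. For shRNA1 they were 42494046 to 61995492 without and 58574217 to 72833921 with DOX, and for shRNA2 58535488 to 67193482 without and 59228180 to 67781862 with DOX. Over the 1000 most variable genes, the first principal component held 42.1% of the variance and set the control libraries (−34.0 to −27.0) apart from those of both TRA2B hairpins (11.7 to 24.6). The second held 21.1% and set the libraries without DOX (−24.4 to −6.45) apart from those with DOX (5.53 to 23.1). The shRNA1 library without DOX of replicate 1 stood apart, with 89.9% of its counts in protein-coding genes and 2.96% in mitochondrial ribosomal RNA. RMRP, a noncoding RNA made without a poly(A) tail, reached 503 CPM there, against 0.291 and 0.283 CPM in replicates 2 and 3.

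TRA2B, a splicing activator that binds exonic enhancers, fell under DOX with both hairpins against it. With shRNA1 it went from 188 ± 13.8 to 116.2 ± 18.2 CPM (SD, n = 3 libraries per group, as throughout), a log2 fold change of −0.69 ± 0.11 (SE) that left 61.9% of the transcript (edgeR adjusted p = 0.000132). With shRNA2 it went from 153 ± 10.9 to 43.2 ± 7.17 CPM, a log2 fold change of −1.83 ± 0.11 that left 28.2% (edgeR adjusted p = 4.03e-10). In the control it stood at 170 ± 12.5 CPM without and 188 ± 8.50 CPM with DOX (log2 fold change 0.14 ± 0.11, edgeR adjusted p = 0.38). The DOX effects of the hairpins on TRA2B (ENSG00000136527.17_1) differed by 1.14 ± 0.15 on the log2 scale (edgeR adjusted p = 0.00053). Without DOX, TRA2B differed from the control by 0.14 with shRNA1 (edgeR adjusted p = 0.296) and by −0.15 with shRNA2 (edgeR adjusted p = 0.255).

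**Figure D1:**
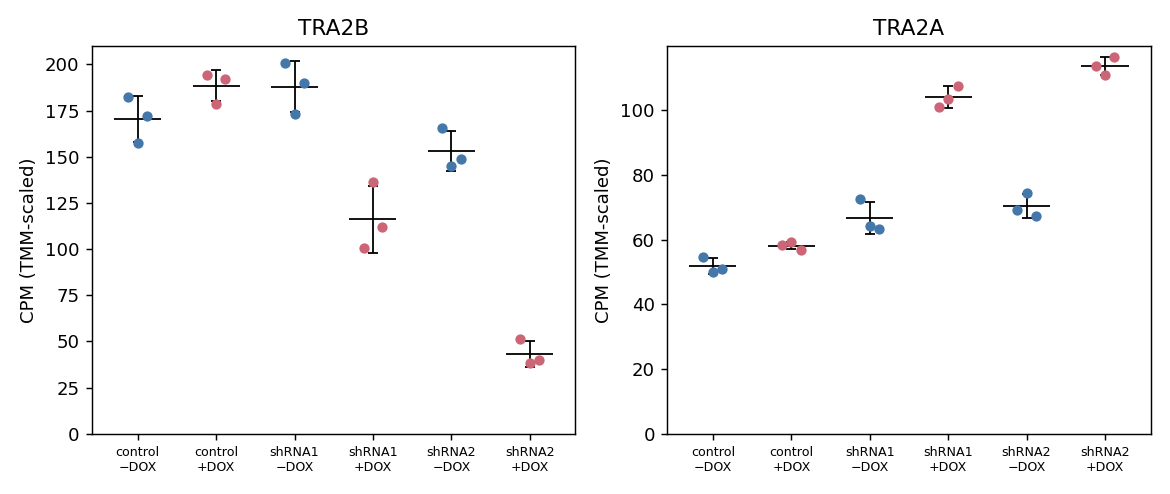
TRA2B (left) and TRA2A (right) in TMM-scaled CPM in the 6 groups. Points are single libraries, the horizontal line is the mean and the bars are the SD of 3 libraries. With DOX, TRA2B averaged 116.2 CPM with shRNA1 and 43.2 CPM with shRNA2, against 188 CPM in the control.

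TRA2A, the paralogue of TRA2B, rose under DOX with both hairpins against TRA2B. It went from 66.7 ± 4.97 to 104 ± 3.34 CPM with shRNA1 (log2 fold change 0.64 ± 0.060, edgeR adjusted p = 1.21e-07) and from 70.3 ± 3.65 to 114 ± 2.85 CPM with shRNA2 (0.69 ± 0.060, edgeR adjusted p = 1.6e-08). The control value was 52.0 ± 2.44 CPM without and 58.1 ± 1.14 CPM with DOX (0.16 ± 0.060, edgeR adjusted p = 0.0578), and the mean of both hairpins exceeded the control DOX effect by 0.50 ± 0.073 (edgeR adjusted p = 3.19e-05). Unlike those on TRA2B, the hairpins' DOX effects on TRA2A had no called difference (−0.050 ± 0.084, edgeR adjusted p = 0.864). Without DOX, TRA2A (ENSG00000164548.10_1) was higher than in the control, by 0.36 with shRNA1 (edgeR adjusted p = 5.74e-05) and by 0.44 with shRNA2 (edgeR adjusted p = 5.51e-06). Among the 12 tested members of the SR and TRA2 family, 1 rose and 1 fell with shRNA1, these being TRA2A and TRA2B, and 3 rose and 3 fell with shRNA2. The counts adjusted over the list alone were the same. SRSF7 rose by 0.24 and SRSF11 fell by 0.34 on the log2 scale with shRNA2 (edgeR adjusted p = 0.00327 and 0.00347). The mean of both hairpins had no called difference from the control for either (edgeR adjusted p = 0.563 and 0.389). SRSF4 alone rose in the control, by 0.19 (edgeR adjusted p = 0.0118). It lost that call without its libraries without DOX of replicates 2 and 3 and the one with DOX of replicate 2 (edgeR adjusted p = 0.0538, 0.0506 and 0.0931). In the control the list as a whole reached a camera adjusted p of 0.0428 (adjusted p = 0.21 with an estimated correlation). Camera gave adjusted p = 0.698 with shRNA1 and 0.831 with shRNA2 for this list. Fits that leave out 1 library gave 2 raised genes with shRNA1 in 1 of 18 and 2 lowered ones in 3 of 18, and in the control 3 raised genes without its no-DOX replicate 1 and 2 without the shRNA1 no-DOX replicate 1.

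Other splicing regulators moved in both directions. HNRNPA3, HNRNPA2B1 and HNRNPAB, RNA-binding proteins of the hnRNP class, rose with shRNA1 by 0.38, 0.40 and 0.29 and with shRNA2 by 0.45, 0.40 and 0.50 on the log2 scale (largest edgeR adjusted p = 0.000745). HNRNPA3 and HNRNPA2B1 rose in the control too, by 0.28 and 0.26 (edgeR adjusted p = 0.00497 and 0.0138). Their mean with both hairpins did not differ from it by a called amount (edgeR adjusted p = 0.261 and 0.295). For HNRNPAB the control stood at 0.12 (edgeR adjusted p = 0.122) and the mean of both hairpins exceeded it by 0.27 (edgeR adjusted p = 0.0052). CELF2 fell by 0.49 with shRNA1 and 0.34 with shRNA2, with a control value of −0.24 (edgeR adjusted p = 0.0606) and no called difference (edgeR adjusted p = 0.268). MBNL2 fell by 0.41 and 0.53, and the mean of both hairpins lay below the control (−0.67, edgeR adjusted p = 0.000532). Among 47 tested genes of this list 11 rose and 5 fell with shRNA1 (11 and 5 adjusted over the list alone). With shRNA2 12 rose and 7 fell (12 and 8 adjusted over the list alone), and 9 rose and 2 fell in the control (9 and 5 adjusted over the list alone). The list was not called by camera in these comparisons (adjusted p = 0.48, 0.538 and 0.131). Of 15 nonsense-mediated decay factors, 2 rose with shRNA1, 4 rose and 1 fell with shRNA2, and 4 rose and 2 fell in the control (adjusted over the list alone, 1 rose with shRNA1, and the other counts were the same). UPF3B, which links exon junctions to decay, rose in each, by 0.37, 0.58 and 0.30 on the log2 scale (edgeR adjusted p = 0.00157, 5.82e-06 and 0.00729), and camera did not call the list (adjusted p = 0.168, 0.0841 and 0.453). With single libraries left out, the raised regulators with shRNA1 numbered 6 and 7 without its no-DOX replicates 1 and 2 and 7, 7 and 5 without its DOX replicates 1, 2 and 3, and the lowered ones 3 without no-DOX replicate 2 or DOX replicates 2 or 3. With shRNA2, 7 rose without its DOX replicate 3. In the control 3 rose without no-DOX replicate 2 and 7 fell without DOX replicate 1. Of the decay factors raised with shRNA1, RBM8A lost its call in 16 of 18 such fits, with a log2 fold change of 0.25 (edgeR adjusted p = 0.234) without DOX replicate 3. In the control 1 decay factor rose without no-DOX replicates 2 or 3 and 2 without DOX replicate 2, and 1 fell in 5 of 18 fits. The gene lowered with shRNA2 lost its call in 4 of 18.

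In the control construct, the background of the other comparisons, inflammatory, hypoxia and matrix transcripts were lower with DOX. Lane and treatment cannot be told apart in these libraries. C3, the central complement protein, went from 726 ± 169 to 17.6 ± 1.16 CPM (log2 fold change −5.37 ± 0.19, edgeR adjusted p = 2.73e-11). IL1B, a proinflammatory cytokine, went from 236 ± 79.0 to 15.4 ± 0.846 CPM, and PTGS2, an inducible enzyme of prostaglandin synthesis, from 233 ± 75.5 to 15.1 ± 2.96 CPM (edgeR adjusted p = 1.63e-08 and 7.71e-09). CSF3, CXCL3, CXCL1, SAA2 and ASB2 fell by 4.30, 4.22, 3.84, 3.68 and 3.66 on the log2 scale. The genes that rose most were MIR30A (0.865 ± 0.0709 to 15.2 ± 1.37 CPM), ENOX1, ZNF641, SAMD9L, CLU, C21orf91, ID2 and CENPT, with log2 fold changes from 4.13 for MIR30A to 1.82 for CENPT (largest edgeR adjusted p = 4.2e-09). MIR30A is the gene of a microRNA precursor, ID2 an inhibitor of helix-loop-helix factors and CENPT a kinetochore protein.

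Across the gene lists, 24 of 25 tested NF-kB and inflammatory cytokine genes fell in the control and the other was not called (25 fell adjusted over the list alone). Their median log2 fold change was −1.90 (camera adjusted p = 6.75e-31; adjusted p = 0.0541 with an estimated correlation). Hypoxia and glycolysis genes fell in 27 of 32 cases, the other 5 not being called (29 adjusted over the list alone; camera adjusted p = 9.18e-18; adjusted p = 0.0737 with an estimated correlation). VEGFA fell by 1.90, CA12 by 1.52 and the oxygen sensor EGLN3 by 1.19 on the log2 scale. Of 41 matrix and integrin genes 23 fell and 8 rose (24 and 9 adjusted over the list alone). MMP1, an interstitial collagenase, fell by 3.06 and MMP9 by 2.96 on the log2 scale (camera adjusted p = 9.78e-06; adjusted p = 0.15 with an estimated correlation). In the unfolded protein response 10 of 20 genes fell and 10 were not called (13 fell adjusted over the list alone), including the stress sensor ERN1 by 1.11 and the chaperone HSPA5 by 0.41 (camera adjusted p = 3.5e-06; adjusted p = 0.102 with an estimated correlation). Sterol and fatty acid synthesis went up instead, with 19 of 28 genes rising and 9 not called (21 adjusted over the list alone), among them the regulator SREBF1 by 1.16 and INSIG1 by 0.91 (camera adjusted p = 2.68e-11; adjusted p = 0.206 with an estimated correlation). Proliferation genes rose in 21 of 37 cases, with 16 not called (31 adjusted over the list alone), with CENPA up by 0.53 and NDC80 by 0.47 (camera adjusted p = 3.82e-09; adjusted p = 0.415 with an estimated correlation). DNA replication and repair genes rose in 12 of 37 cases, with 25 not called (14 adjusted over the list alone), with PCNA up by 0.39 (camera adjusted p = 1.41e-05; adjusted p = 0.456 with an estimated correlation). Interferon response genes rose in 17 of 36 cases and fell in 2 (19 and 2 adjusted over the list alone; camera adjusted p = 8.02e-06; adjusted p = 0.102 with an estimated correlation). The integrated stress response rose in 18 of 35 genes and fell in 4 (20 and 5 adjusted over the list alone; camera adjusted p = 0.00184; adjusted p = 0.415 with an estimated correlation). The respiratory chain with the mitochondrial ribosome rose in 16 of 47 (20 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.17e-05; adjusted p = 0.415 with an estimated correlation). Several of these counts rested on single control libraries. Raised proliferation genes numbered 34, 2 and 3 without the no-DOX replicates 1, 2 and 3 and 11, 10 and 7 without the DOX replicates 1, 2 and 3. Raised DNA replication and repair genes numbered 26, 4 and 4 without the no-DOX replicates 1, 2 and 3. Raised respiratory chain genes numbered 9 and 7 without the no-DOX replicates 2 and 3 and 7 and 9 without the DOX replicates 2 and 3. Lowered unfolded protein response genes numbered 6 without no-DOX replicate 3, and of the 2 lowered interferon genes at least 1 call was lost in 16 of 18 fits.

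In all, 4705 genes were called for DOX in the control construct by edgeR, 2277 higher and 2428 lower (2334 and 2267 when libraries were scaled by their totals alone), of which 216 higher and 432 lower changed at least 2-fold. The count was 2858 when only the 6 control libraries were fitted, 3045 (1338 higher, 1707 lower) without the control library without DOX of replicate 2 and 3044 (1336 higher, 1708 lower) without that of replicate 3. Every control library without DOX came from a single lane and every one with DOX from another, so no value within a lane exists for this effect.

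With shRNA1, DOX raised MIR30A, RGS16, ATP6V0D2, ENOX1, ST14 and interferon-related genes and lowered hypoxia genes. MIR30A went from 1.26 ± 0.0973 to 82.8 ± 8.36 CPM (log2 fold change 6.03 ± 0.11, edgeR adjusted p = 4.04e-20), while its tested neighbours OGFRL1, MIR30C2 and LINC00472 changed by at most 0.55 in any construct. RGS16, which dampens G protein signalling, went from 0.723 ± 0.122 to 7.86 ± 1.95 CPM, and ST14, the membrane protease matriptase, from 0.823 ± 0.119 to 4.99 ± 0.404 CPM (edgeR adjusted p = 1.59e-10 and 9.75e-11). ATP6V0D2, a proton pump subunit, rose by 3.56, ENOX1 by 3.29, SAMD9L by 2.64 and ZNF641 by 2.32 on the log2 scale, and RALGPS2-AS1 went from 1.11 ± 0.201 to 6.18 ± 1.00 CPM (largest edgeR adjusted p = 1.65e-09). CA9, a carbonic anhydrase induced by low oxygen, went from 20.9 ± 2.54 to 4.76 ± 0.635 CPM, and fibronectin (FN1) from 1638 ± 133 to 584 ± 50.8 CPM (edgeR adjusted p = 9.43e-10 and 7.65e-10). TMOD2, POM121L9P, C4orf47, CPNE7, LINC01293 and LRRC56 fell by 2.12, 1.85, 1.82, 1.75, 1.52 and 1.46 (largest edgeR adjusted p = 1.92e-05).

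Among the lists, 27 of 32 hypoxia and glycolysis genes fell with shRNA1 and 5 were not called (29 fell adjusted over the list alone; camera adjusted p = 1.58e-20; adjusted p = 0.0876 with an estimated correlation). PFKFB4, an activator of glycolysis, fell by 1.14 and ALDOC by 0.98. The integrated stress response rose in 20 of 35 genes and fell in 2 (22 and 4 adjusted over the list alone; camera adjusted p = 2.99e-06; adjusted p = 0.314 with an estimated correlation). The stress-induced factor DDIT3 rose by 0.77 and the tRNA synthetase WARS1 by 0.45. Interferon response genes rose in 16 of 36 cases and fell in 2 (19 and 2 adjusted over the list alone). ISG15, a ubiquitin-like interferon product, went from 17.6 ± 1.32 to 38.1 ± 4.57 CPM, and OASL and SAMD9 rose by 0.94 and 1.02 (camera adjusted p = 5.56e-06; adjusted p = 0.161 with an estimated correlation). This list was not called for shRNA1 minus the control (camera adjusted p = 0.642). Proliferation genes rose in 14 of 37 cases, with 23 not called (16 adjusted over the list alone), with CDC20 up by 0.93 and CENPA by 0.67 (camera adjusted p = 2.99e-06; adjusted p = 0.714 with an estimated correlation). Nuclear genes of the respiratory chain and mitochondrial ribosome rose in 17 of 47 cases and 1 fell (20 and 1 adjusted over the list alone), with UQCRFS1 up by 0.64 (camera adjusted p = 4.38e-06; adjusted p = 0.613 with an estimated correlation). The unfolded protein response rose in 4 of 20 genes and fell in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.038; adjusted p = 0.613 with an estimated correlation). Sterol and fatty acid synthesis fell in 8 of 28 genes and rose in 1, SREBF1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0331; adjusted p = 0.715 with an estimated correlation). Single libraries moved some counts. Raised proliferation genes numbered 3 and 8 without the shRNA1 no-DOX replicates 1 and 2, 4 without its DOX replicate 3 and 9 without the control DOX replicate 2. Raised respiratory chain genes numbered 6 without no-DOX replicate 1 and 10 without DOX replicate 3, and their lowered gene lost its call in 3 of 18 fits. Raised unfolded protein response genes numbered 1 without no-DOX replicate 1, where XBP1 and HSPA5 were not called (edgeR adjusted p = 0.0927 and 0.0863), and 2 without DOX replicate 2. Lowered sterol genes numbered 13 without the control no-DOX replicate 1, 5 and 4 without the shRNA1 no-DOX replicates 2 and 3, and 3, 3 and 4 without its DOX replicates 1, 2 and 3. Their raised genes numbered 2 in 3 of 18 fits. Lowered stress response genes numbered 4 without the control DOX replicate 2, and lowered interferon genes numbered at most 1 in 5 of 18 fits.

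NF-kB and inflammatory genes rose in 5 of 25 cases and fell in 6 (5 and 6 adjusted over the list alone), with IL24 up by 1.19 and TNFAIP2 down by 0.37, at a median of −0.068, a mean of 0.079 and a camera adjusted p of 0.79. Without the no-DOX replicate 3, 3 rose. For shRNA1, edgeR called 4982 genes, 2484 higher and 2498 lower with DOX (2695 and 2253 when scaled by totals alone), of which 302 and 307 changed at least 2-fold. Without the library without DOX of replicate 1, which stood apart in ribosomal and noncoding RNA, the count was 3621 (1535 higher, 2086 lower), as it was without the library with DOX of replicate 3 (1825 higher, 1796 lower). Libraries with and without DOX came from different lanes.

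With shRNA2, which left less TRA2B, MIR30A, RGS16, ATP6V0D2, ENOX1 and ST14 led again and inflammatory genes rose as well. MIR30A went from 1.38 ± 0.141 to 73.2 ± 1.06 CPM, RGS16 from 0.932 ± 0.260 to 23.4 ± 3.41 CPM, and ATP6V0D2 from 0.468 ± 0.0336 to 10.1 ± 0.969 CPM (largest edgeR adjusted p = 3.9e-13). IL1A, a cytokine of the interleukin-1 family, went from 5.11 ± 0.445 to 37.7 ± 2.80 CPM (log2 fold change 2.88 ± 0.16, edgeR adjusted p = 8.72e-11). ENOX1, ST14, RALGPS2-AS1 and the transporter gene SLC22A23 rose by 3.65, 2.95, 2.93 and 2.81 on the log2 scale (largest edgeR adjusted p = 2.37e-11). CA9 went from 22.6 ± 0.766 to 2.31 ± 0.196 CPM and the embryonic myosin gene MYH3 from 15.0 ± 0.873 to 3.37 ± 0.288 CPM (edgeR adjusted p = 1.7e-12 and 3.47e-12). ALPP, IFITM10, the inhibin subunit gene INHBB, C4orf47, the mucin gene MUC5B and TMOD2 fell by 2.66, 2.62, 2.34, 2.27, 2.07 and 2.07 on the log2 scale (largest edgeR adjusted p = 0.000117).

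Of 25 NF-kB and inflammatory genes 17 rose and 2 fell with shRNA2 (17 and 3 adjusted over the list alone), with CXCL3 up by 2.02, IL24 by 2.35 and CSF2 by 1.38 (camera adjusted p = 5.07e-06; adjusted p = 0.41 with an estimated correlation). Hypoxia and glycolysis genes fell in 26 of 32 cases, with 6 not called (26 adjusted over the list alone), with NDRG1 down from 1477 ± 67.8 to 426 ± 17.2 CPM (camera adjusted p = 2.85e-15; adjusted p = 0.211 with an estimated correlation). The integrated stress response rose in 25 of 35 genes and fell in 3 (26 and 3 adjusted over the list alone), with DDIT3 up by 1.11 and ATF3 by 1.17 (camera adjusted p = 8.43e-09; adjusted p = 0.211 with an estimated correlation). Respiratory chain and mitochondrial ribosome genes rose in 33 of 47 cases and 1 fell (35 and 1 adjusted over the list alone), with UQCRFS1 up by 0.78 and SDHB by 0.54 (camera adjusted p = 1.2e-09; adjusted p = 0.295 with an estimated correlation). Cytosolic ribosomal protein genes rose in 25 of 47 cases, with 22 not called (29 adjusted over the list alone), RPS12 by 0.43 and RPL8 by 0.37 (camera adjusted p = 5.07e-06; adjusted p = 0.583 with an estimated correlation). EdgeR and DESeq2 each called 0 of the 47 with shRNA1 and in the control, where 0 and 2 had an unadjusted edgeR p below 0.05 (camera adjusted p = 0.686 and 0.962). Proliferation genes rose in 20 of 37 cases, with 17 not called (26 adjusted over the list alone; camera adjusted p = 2.09e-06; adjusted p = 0.583 with an estimated correlation). The unfolded protein response rose in 11 of 20 genes and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000459; adjusted p = 0.295 with an estimated correlation). Interferon response genes rose in 14 of 36 cases and fell in 3 (15 and 3 adjusted over the list alone; camera adjusted p = 0.0029; adjusted p = 0.295 with an estimated correlation). With single libraries left out, raised proliferation genes numbered 13 without the shRNA2 no-DOX replicate 2 or DOX replicate 3, raised cytosolic ribosomal protein genes 13 without its DOX replicate 1, and lowered interferon genes 1 without replicate 2 of either arm. The lowered unfolded protein response gene lost its call in 11 of 18 fits and the lowered respiratory chain gene in 4.

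In this construct edgeR called 7879 genes, 4142 higher and 3737 lower (3568 and 4162 when scaled by totals alone, and 3705 and 3947 with no filter on low counts), of which 437 higher and 758 lower changed at least 2-fold. Libraries with the same number shared a lane with and without DOX, and with the lane held fixed by the replicate block 8747 genes were called, with TRA2B at −1.84.

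**Figure D2:**
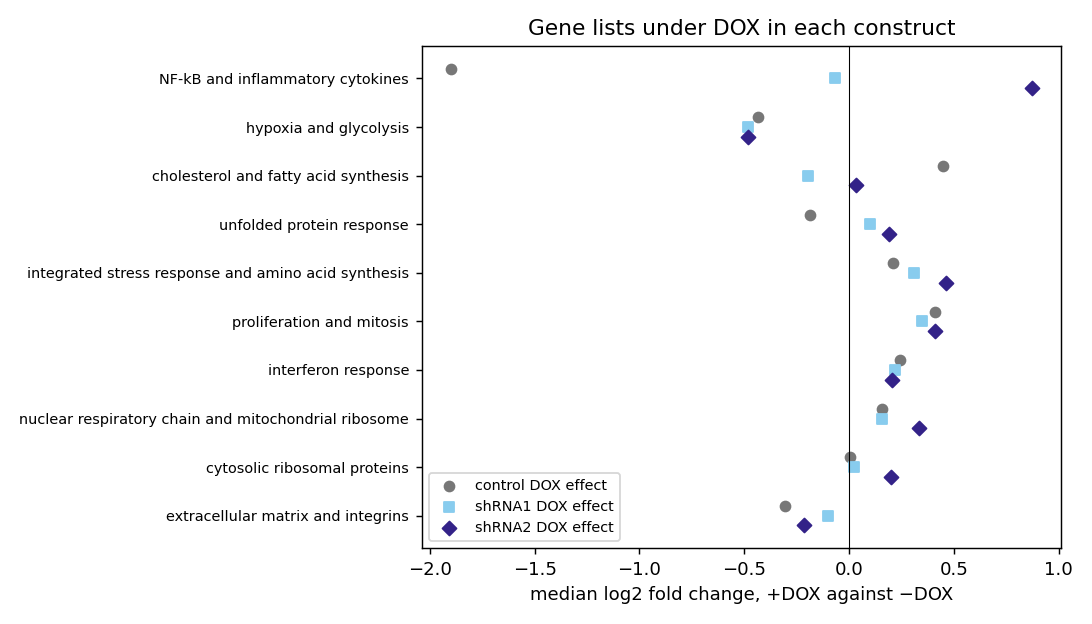
Median log2 fold change with DOX of the tested members of each gene list, for the control, shRNA1 and shRNA2. The median of NF-kB and inflammatory genes was −1.90 in the control, −0.068 with shRNA1 and 0.87 with shRNA2, and that of hypoxia and glycolysis genes lay between −0.48 and −0.44 in all 3 constructs.

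The hairpins against TRA2B shared many changes. Of the genes raised by each, 1940 were raised by both, where independent lists would share 488, and 1898 were lowered by both, where independent lists would share 443 (odds ratios 26.6 and 28.8). With relative log expression factors the lowered genes were more numerous (1815 raised and 1992 lowered), as they were without the shRNA1 library without DOX of replicate 1 (1223 and 1701). Opposite calls were made for 22 genes. Log2 fold changes correlated across the 21089 genes at a Pearson r of 0.656 and a Spearman rho of 0.655, with genes not being independent replicates. Part of this was common to the control, which shared 746 raised and 821 lowered genes with shRNA1 (268 and 288 for independent lists) and 892 and 801 with shRNA2 (447 and 430 for independent lists). Changes in all 3 constructs were found for 620 raised and 614 lowered genes, where independent lists would share 53 and 51. These comparisons have no library in common.

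A total of 978 genes were raised by both hairpins and also in their mean against the control, and 941 were lowered. Of these, 857 of the raised and 757 of the lowered genes had the larger estimate with shRNA2, and 45 and 49 of those were called between the hairpins. ST14 exceeded the control DOX effect by 2.32 ± 0.19 on the log2 scale, RGS16 by 2.27 ± 0.22, ATP6V0D2 by 2.22 ± 0.19, MIR30A by 1.75 ± 0.14 and SLC22A23 by 1.37 ± 0.15 (largest edgeR adjusted p = 1.23e-06). RALGPS2-AS1, ENOX1, DACH1, CENPT and TSNAXIP1 exceeded it by 2.86, 0.92, 0.60, 0.29 and 0.26. CA9 lay below the control DOX effect (−1.35 ± 0.22, edgeR adjusted p = 0.000105), as did C4orf47 (−1.19 ± 0.20) and the actin-binding villin relative AVIL (−1.16 ± 0.13). ALPP, LRRC56, DEPP1, SAP30-DT, ADAM22, TCAF2 and TMOD2 completed the genes named here, with differences from −2.70 for ALPP to −0.41 for TMOD2 (largest edgeR adjusted p = 0.045). Single left-out libraries ended some of these calls. TSNAXIP1 lost its call in 13 of the 18 fits that leave out 1 library and TMOD2 in 12 (edgeR adjusted p up to 0.171 and 0.136). Without control libraries without DOX, replicate 1 ended the calls of LRRC56 and TCAF2 (edgeR adjusted p = 0.0516 and 0.0504) and replicate 2 that of CENPT (0.111). Without control libraries with DOX, replicate 1 ended those of CENPT and ADAM22 (0.0704 and 0.0505), replicate 2 that of DEPP1 (0.0532) and replicate 3 those of CENPT and DEPP1 (0.0664 and 0.0539).

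**Figure D3:**
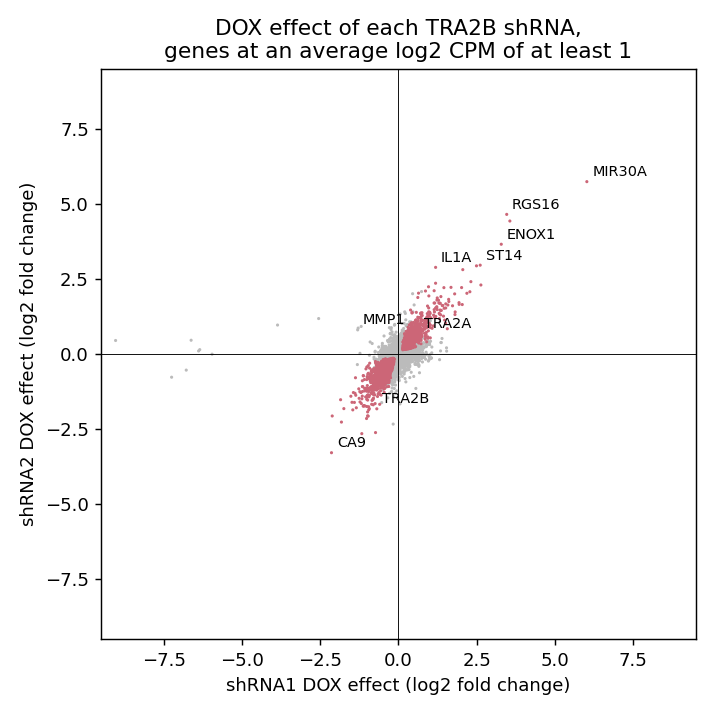
Log2 fold change with DOX of shRNA1 (horizontal) and shRNA2 (vertical) for each gene at an average log2 CPM of at least 1. Red points are genes called with both hairpins in the same direction and grey points are the others; over all tested genes, 1940 were raised and 1898 lowered by both.

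Relative to the control, the inflammatory genes were the group that differed most in size. The mean DOX effect of both hairpins minus that of the control was 5.60 ± 0.22 for C3, 5.55 ± 0.21 for the chemokine CXCL3, 5.17 ± 0.26 for IL1B, 5.12 ± 0.19 for SERPINB2 and 5.02 ± 0.20 for IL1A (largest edgeR adjusted p = 7.64e-09). The levels behind these differences were not alike. C3 stood at 43.8 ± 3.78 CPM without and 51.0 ± 11.2 CPM with DOX for shRNA1, and at 40.5 ± 3.28 and 48.0 ± 1.45 CPM for shRNA2 (edgeR adjusted p = 0.363 and 0.269), while the control went from 726 to 17.6 CPM. IL1B went from 35.7 ± 3.43 to 143 ± 2.70 CPM with shRNA2 (edgeR adjusted p = 3.76e-06) and stood at 24.2 ± 1.68 and 33.2 ± 6.75 CPM with shRNA1 (edgeR adjusted p = 0.13). C3 and IL1B do not stand for the others, since IL1A rose with shRNA1 as well, though by less than with shRNA2. The largest negative differences were those of ALPP (−2.70 ± 0.35), SCIN (−2.29 ± 0.25), RGCC (−2.10 ± 0.13), SDR16C5 (−2.09 ± 0.23) and INHBB (−2.09 ± 0.35), with edgeR adjusted p at most 0.000505.

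**Figure D4:**
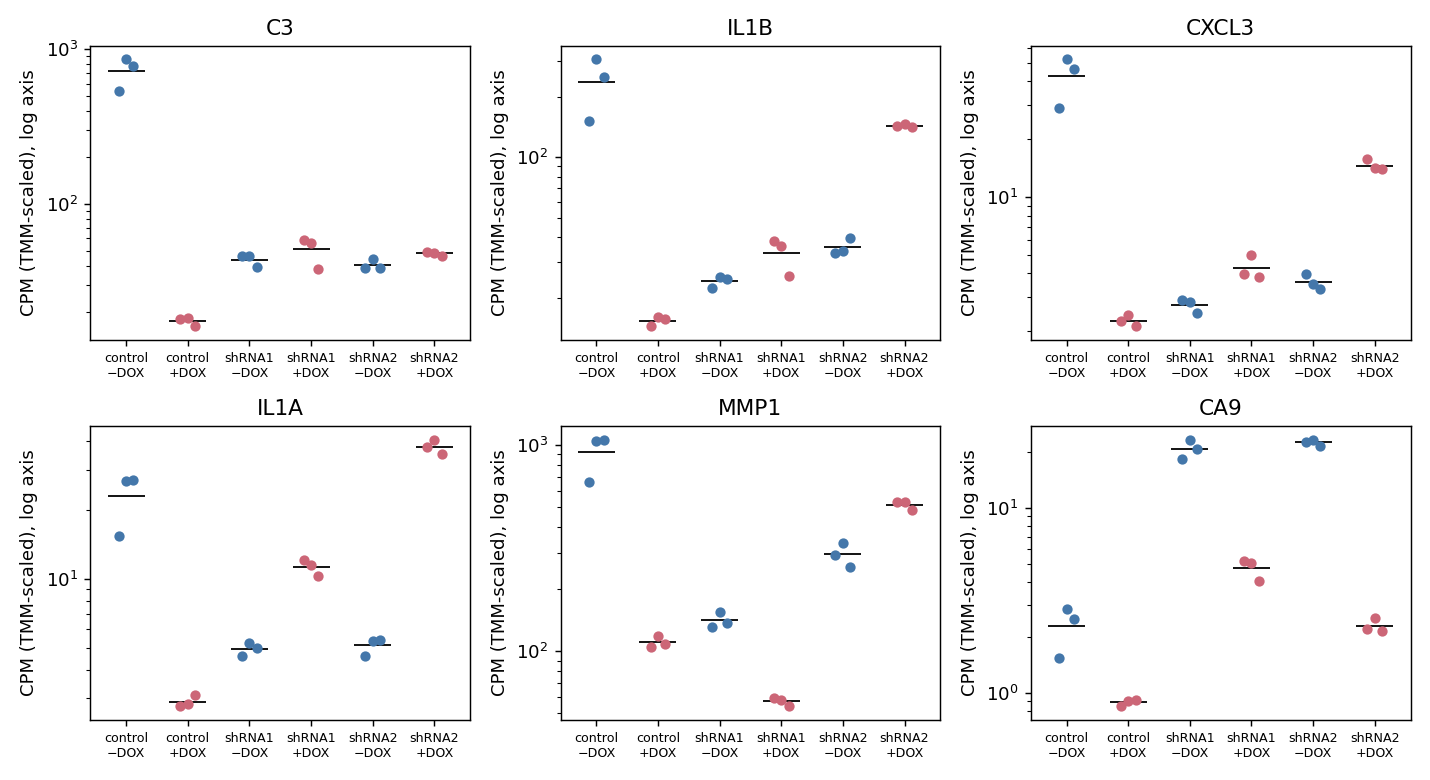
Levels of C3, IL1B, CXCL3, IL1A, MMP1 and CA9 in TMM-scaled CPM on a log axis in the 6 groups. Points are single libraries and lines are means of 3; C3 averaged 726 CPM in the control without DOX and 17.6 to 51.0 CPM in the other groups.

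By list, the mean of both hairpins lay above the control for 24 of 25 NF-kB and inflammatory genes and below it for 1 (24 and 1 adjusted over the list alone), with a median of 3.36 (camera adjusted p = 3.1e-26; adjusted p = 0.0474 with an estimated correlation). The unfolded protein response lay above for 16 of 20 genes, with 4 not called (19 adjusted over the list alone), with HSPA5 at 0.79, ERN1 at 1.23 and PDIA4 at 0.56 (camera adjusted p = 1.47e-09; adjusted p = 0.0474 with an estimated correlation). Sterol and fatty acid synthesis lay below for 21 of 28 genes, with 7 not called (22 adjusted over the list alone), among them SCD (−1.10), IDI1 (−1.14) and INSIG1 (−0.77; camera adjusted p = 9.03e-10; adjusted p = 0.526 with an estimated correlation). With shRNA2 itself, 6 of these genes rose and 1 fell under DOX (5 and 1 adjusted over the list alone). Their median there was 0.032 (camera adjusted p = 0.504), against 0.447 in the control and −0.198 with shRNA1. The lowered genes with shRNA2 numbered 0 to 3 in 8 of 18 fits that leave out 1 library. The lung metastasis signature lay above for 8 of 15 genes and below for 5 (9 and 5 adjusted over the list alone; camera adjusted p = 0.0284; adjusted p = 0.566 with an estimated correlation). Its TNC, a matrix glycoprotein, was at 2.10, MMP1 at 2.81 and KYNU at 2.59. Under DOX itself 3 of the signature's 15 genes rose and 2 fell with shRNA1, and 8 rose and 3 fell with shRNA2 (camera adjusted p = 0.629 and 0.145). In the control 4 rose and 7 fell (camera adjusted p = 0.0747). MMP1 was lower with DOX than without it in shRNA1. Matrix and integrin genes lay above for 17 of 41 and below for 9 (19 and 10 adjusted over the list alone), with TIMP3, an inhibitor of metalloproteinases, at −1.03 (camera adjusted p = 0.0313; adjusted p = 0.566 with an estimated correlation). Under DOX itself 8 of these genes rose and 13 fell with shRNA1, and 10 rose and 17 fell with shRNA2 (camera adjusted p = 0.138 and 0.0944). Their medians there were −0.101 and −0.213, against −0.307 in the control. The integrated stress response lay above for 16 of 35 genes and below for 1 (18 and 3 adjusted over the list alone; camera adjusted p = 0.00795; adjusted p = 0.566 with an estimated correlation). DNA replication and repair lay below for 6 of 37 and above for 1 (5 and 0 adjusted over the list alone; camera adjusted p = 0.0329; adjusted p = 0.764 with an estimated correlation). PCNA, the replication clamp, was at −0.77. Under DOX itself 2 of the 37 replication and repair genes rose and 1 fell with shRNA1, and 9 rose and 2 fell with shRNA2 (camera adjusted p = 0.48 and 0.168). Their medians there were 0.0562 and 0.113, against 0.182 in the control. Mitochondrially encoded mRNAs lay below for 6 of 13, with 7 not called (7 below adjusted over the list alone; camera adjusted p = 0.0313; adjusted p = 0.764 with an estimated correlation). Cytosolic ribosomal proteins lay above for 3 of 47, with 44 not called (1 above adjusted over the list alone; camera adjusted p = 0.0313; adjusted p = 0.764 with an estimated correlation). Hypoxia and glycolysis was not called (7 above and 11 below of 32, 7 and 14 adjusted over the list alone, camera adjusted p = 0.0757), nor was proliferation (camera adjusted p = 0.832). Of its 37 genes edgeR called 0 and DESeq2 1, and 4 had an unadjusted edgeR p below 0.05. Interferon response (6 above and 6 below of 36) was not called for the mean either (camera adjusted p = 0.891). Nor was the respiratory chain with the mitochondrial ribosome (6 above and 2 below of 47, camera adjusted p = 0.0859), though it was for shRNA2 minus the control (camera adjusted p = 0.00772, and 0.656 with an estimated correlation). Single libraries moved some of these counts. Mitochondrially encoded mRNAs below the control numbered 1 and 2 without the control no-DOX replicates 1 and 3, 3 without its DOX replicate 2 and none without its DOX replicate 3. They numbered 3 without the shRNA1 DOX replicate 3 and without replicate 2 of either shRNA2 arm. Cytosolic ribosomal proteins above it numbered 1 without the control no-DOX replicate 2, 8 without its DOX replicate 2 and 1 without its DOX replicate 3. Without the control no-DOX replicate 1, 13 DNA replication and repair genes and 4 stress response genes lay below, and 2 of the latter without the shRNA2 DOX replicate 1. Without the control no-DOX replicate 2, 3 hypoxia genes lay above. The DNA replication gene above lost its call in 15 of 18 fits and the inflammatory gene below in 6. Camera did not call mitochondrially encoded mRNAs, cytosolic ribosomal proteins or the stress response for shRNA1 minus the control (adjusted p = 0.0954, 0.857 and 0.106). It called each for shRNA2 minus the control (adjusted p = 0.0174, 0.000235 and 0.00044, and 0.656 for each with an estimated correlation).

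The mean of both hairpins differed from the control in 5045 genes by edgeR, 2655 above and 2390 below (2442 and 2532 when scaled by totals alone). Taken singly, shRNA1 differed from the control in 2631 genes (1442 above, 1189 below; 923 and 881 without the control no-DOX replicate 2) and shRNA2 in 5184 (2782 above, 2402 below; 2348 and 2740 when scaled by totals alone). All these differences rest on the control libraries whose lanes follow the treatment.

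The hairpins differed from each other in few genes, and the inflammatory genes were among them. The DOX effect of shRNA1 lay below that of shRNA2 for MMP1 (−2.11 ± 0.20), which went from 141 ± 12.9 to 57.1 ± 2.76 CPM with shRNA1 and from 295 ± 39.1 to 513 ± 26.7 CPM with shRNA2 (edgeR adjusted p = 2.76e-05). WTAPP1 (−2.15 ± 0.20), which overlaps MMP1, ENTPD3 (−2.11 ± 0.24), IL1A (−1.69 ± 0.22) and IL1B (−1.55 ± 0.29) differed in the same direction (largest edgeR adjusted p = 0.0183). INHBB (2.17 ± 0.44), IFITM10 (1.89 ± 0.28), the cadherin gene DCHS1 (1.45 ± 0.18), EPC1-AS2 (1.25 ± 0.24) and HCAR1 (1.20 ± 0.21) differed in the other (largest edgeR adjusted p = 0.0267). INHBB lost its call in 10 of the 18 fits that leave out 1 library (edgeR adjusted p up to 0.0897), and IL1B without shRNA1 replicate 3 or shRNA2 replicate 1, both without DOX (edgeR adjusted p = 0.0557 and 0.0608). Of 25 NF-kB and inflammatory genes, 7 were lower with shRNA1 and 18 were not called (18 lower adjusted over the list alone; camera adjusted p = 2.81e-15; adjusted p = 0.24 with an estimated correlation). Cytosolic ribosomal proteins had 0 of 47 genes called by edgeR (0 adjusted over the list alone) and 0 by DESeq2, with 18 at an unadjusted edgeR p below 0.05, at a median of −0.20 (camera adjusted p = 1.9e-09; adjusted p = 0.469 with an estimated correlation). The integrated stress response had 2 of 35 genes lower (8 adjusted over the list alone, camera adjusted p = 1.52e-05; adjusted p = 0.44 with an estimated correlation). Mesenchymal markers had 2 of 19 higher, PDGFRB and TGFBI (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0149; adjusted p = 0.24 with an estimated correlation). TGFBI lost its call in 13 of the 18 fits that leave out 1 library. The 7 inflammatory genes became 13 without the control no-DOX replicate 1 and 4 without the shRNA2 no-DOX replicate 1. The lower stress response genes were TRIB3 and CTH, of which at least 1 lost its call in 15 of 18 fits.

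By edgeR, 256 genes were called between the hairpins, 135 higher and 121 lower with shRNA1, and 188 higher and 68 lower when libraries were scaled by their totals alone. The replicate block gave 514 genes (260 higher, 254 lower), DESeq2 568 (254 higher, 314 lower) and no filter on low counts 730, and 9 of 100 splits of the libraries gave at least as many, the real split among them. Leaving out shRNA1 libraries without DOX gave 169 (replicate 2) and 134 (replicate 3), shRNA1 libraries with DOX 130 (replicate 1) and 153 (replicate 2), shRNA2 libraries without DOX 139 (replicate 1) and 168 (replicate 3), and shRNA2 libraries with DOX 142, 126 and 163 (replicates 1, 2 and 3). Genes lower with shRNA1 numbered 74 without its DOX replicate 3 and 67 without the shRNA2 no-DOX replicate 2.

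Further lists held large changes of single members. Of 13 epithelial markers 1 rose and 6 fell with shRNA1 (1 and 6 adjusted over the list alone) and 3 rose and 5 fell with shRNA2 (3 and 5 adjusted over the list alone; camera adjusted p = 0.104 and 0.454). ST14 was among the raised ones, and the mucin MUC1 and P-cadherin (CDH3) fell by 1.01 and 1.06 with shRNA1 and by 1.75 and 1.89 with shRNA2 (control 0.089 and −0.46, edgeR adjusted p = 0.642 and 0.167). Among 19 mesenchymal markers 3 rose and 6 fell with shRNA1 (4 and 6 adjusted over the list alone) and 4 rose and 7 fell with shRNA2 (5 and 7 adjusted over the list alone). Vimentin (VIM) rose by 0.54, 0.47 and 0.66 in shRNA1, shRNA2 and the control, while FN1 fell by 1.49, 1.61 and 1.37 in shRNA1, shRNA2 and the control (list camera adjusted p = 0.686, 0.147 and 0.269). MMP13, a collagenase, went from 0.0609 ± 0.0250 to 0.885 ± 0.0728 CPM with shRNA1 and from 0.0294 ± 0.0372 to 3.72 ± 0.139 CPM with shRNA2 (edgeR adjusted p = 5.12e-08 and 1.33e-12), and from 0.0826 ± 0.0157 to 0.374 ± 0.0484 CPM in the control (edgeR adjusted p = 6.93e-05). For the p53 pathway 5 of 27 genes rose and 2 fell with shRNA1 (5 and 2 adjusted over the list alone) and 11 rose and 6 fell with shRNA2 (11 and 6 adjusted over the list alone; camera adjusted p = 0.231 and 0.0752). The cell cycle inhibitor CDKN1A rose by 0.52 and 0.91 and the nuclease AEN by 0.59 and 0.98, while they fell by 0.21 and 0.32 in the control (edgeR adjusted p = 0.0239 and 0.0082). TGF-beta and YAP targets had 8 of 23 genes higher and 4 lower with shRNA1 and 5 each with shRNA2 (8 and 5, and 5 and 5, adjusted over the list alone), and the list was not called (camera adjusted p = 0.234 and 0.949). ID3 rose by 1.35 with shRNA1 and from 12.1 ± 1.49 to 29.7 ± 1.59 CPM with shRNA2. The estimate in the control was larger, a rise of 1.68 (edgeR adjusted p = 1.16e-09 against no change). The coagulation initiator F3 fell by 0.71 with shRNA1 and by 1.48 in the control, and was not called with shRNA2 (−0.18, edgeR adjusted p = 0.0808). Of 11 replication-dependent histone genes 2 fell with shRNA1 and 3 with shRNA2 (6 and 3 adjusted over the list alone), such as H2AC6 by 0.36 and 0.81 (control 0.047, edgeR adjusted p = 0.841). The shRNA1 call of H2AC6 was lost without the library that stood apart (−0.16, edgeR adjusted p = 0.271) and without those with DOX of replicates 1 and 3 (edgeR adjusted p = 0.151 and 0.0719). The list was not called (camera adjusted p = 0.0823 and 0.165), and the shRNA1 library that stood apart held 26.6 CPM of H1-4 against 0.501 and 0.676 CPM in its replicates. Lowered histone genes with shRNA1 numbered 8 and 9 without its no-DOX replicates 2 and 3 and 1 without its no-DOX replicate 1 or DOX replicates 1 or 3, and with shRNA2 they numbered 6 without the shRNA1 no-DOX replicate 1. Lowered p53 pathway genes with shRNA1 numbered 1 in 3 of 18 fits.

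Markers of other cells differed in level. Their levels are given as CPM of the library totals, without TMM scaling. PTPRC, CD3E, MS4A1 and AIF1 stayed at or below 0.0721 CPM in the mean of every group, and ESR1, PGR, FOXA1, KRT5, KRT14 and KRT17 at or below 0.340 CPM. Other markers were higher. LAPTM5 stood at 224 to 323 CPM and XBP1 at 82.3 to 113 CPM in all groups, and the highest group means were 11.95 CPM for AGR2, 8.39 for KRT15, 6.44 for OXTR, 4.45 for CD14, 4.18 for TFF3, 3.57 for GATA3 and 1.046 for TP63. Of 10 tested luminal and basal markers 2 rose and 1 fell with shRNA1, and 2 rose and 2 fell with shRNA2 (3 and 1, and 2 and 2, adjusted over the list alone). AGR2, a luminal secretory pathway gene, fell by 1.03 and 1.15 on the log2 scale and rose by 0.79 in the control (edgeR adjusted p = 9.67e-07, 6.56e-08 and 7.27e-06; list camera adjusted p = 0.426, 0.83 and 0.269). Of 4 tested haematopoietic markers 2 rose and 1 fell with shRNA1, and 1 rose and 1 fell with shRNA2, with the same counts adjusted over the list alone (camera adjusted p = 0.48 and 0.996). With single libraries left out, the raised luminal and basal markers with shRNA1 numbered 1 in 11 of 18 fits, the raised haematopoietic ones 1 in 5, and the lowered one lost its call in 3.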

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

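Of the tests given here, those of lower depth and of genomic DNA in a single shRNA1 library were set before their values were seen, and those of RNA without poly(A) tails, of the inflammatory genes, of MIR30A and of other splits of the libraries were chosen after the results had been seen.

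Differences between constructs under the same DOX contrast were tested by edgeR within one fit, with camera for the gene lists, and those that passed are given here. The DOX effect differed from that of the control in 2631 genes and 6 gene lists with shRNA1, in 5184 genes and 8 lists with shRNA2 and in 5045 genes for their mean, and between the hairpins in 256 genes. With an estimated correlation none of these list calls held (adjusted p = 0.0659 to 0.896 for shRNA1 and 0.0506 to 0.656 for shRNA2). Of 32 named changes of the hairpins' DOX effects, 23 differed from the control. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The DOX effects gave 4982, 7879 and 4705 genes for shRNA1, shRNA2 and the control, and the highest other split gave 0 in each. Of 100 splits that regrouped the libraries within each construct, 1, the real one, reached the real count for shRNA1 against the control (2631, highest other 1122), shRNA2 against the control (5184, highest other 3904), the mean against the control (5045, highest other 3603) and genes changed with both hairpins (3838, highest other 2805). A random regrouping of these libraries is argued against there. Chance between cultures is not excluded, since the libraries of a group may not come from separate cultures. Nor can these splits tell treatment from lane in the control and shRNA1. Of these splits, 51 parted all 3 shRNA2 pairs as the real one does, and there too only the real one reached its count for shRNA2 against the control, the mean against the control and genes changed with both hairpins, while the splits that did not part them gave at most 435, 1257 and 0 genes. For the difference between the hairpins, 9 of 100 splits gave 256 genes or more, up to 3599 (9 of the 51 that part the pairs, and at most 1 gene in the others), so chance is not excluded by this count. All 8 others placed most libraries with DOX of one hairpin against most without DOX of the other, as did 53 draws in all, so these counts point to a structure of the samples, the DOX effect shared by both hairpins.

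Genes whose mean DOX effect with both hairpins lay above that of the control were C3 (5.60), CXCL3 (5.55), IL1B (5.17), SERPINB2 (5.12), IL1A (5.02), RALGPS2-AS1 (2.86), ST14 (2.32), RGS16 (2.27), ATP6V0D2 (2.22), MIR30A (1.75), SLC22A23 (1.37), ENOX1 (0.92), DACH1 (0.60), TRA2A (0.50), CENPT (0.29) and TSNAXIP1 (0.26), in log2 units. Those below were ALPP (−2.70), SCIN (−2.29), RGCC (−2.10), SDR16C5 (−2.09), INHBB (−2.09), TRA2B (−1.41), CA9 (−1.35), C4orf47 (−1.19), AVIL (−1.16), LRRC56 (−0.76), DEPP1 (−0.71), SAP30-DT (−0.57), ADAM22 (−0.49), TCAF2 (−0.47) and TMOD2 (−0.41). Between the hairpins, shRNA1 lay above shRNA2 for INHBB (2.17), IFITM10 (1.89), DCHS1 (1.45), EPC1-AS2 (1.25), HCAR1 (1.20) and TRA2B (1.14), and below for WTAPP1 (−2.15), ENTPD3 (−2.11), MMP1 (−2.11), IL1A (−1.69) and IL1B (−1.55). Gene lists that differed between the mean of the hairpins and the control had median log2 differences of 3.36 (NF-kB and inflammatory cytokines), 0.46 (lung metastasis signature), 0.36 (unfolded protein response), 0.22 (extracellular matrix and integrins), 0.20 (integrated stress response), 0.092 (cytosolic ribosomal proteins), −0.11 (DNA replication and repair), −0.22 (mitochondrially encoded mRNAs) and −0.51 (cholesterol and fatty acid synthesis). With an estimated correlation those of NF-kB and of the unfolded protein response held (adjusted p = 0.0474 each), and the other 7 did not (adjusted p = 0.526 to 0.764). Lists that differed between the hairpins had medians of −0.90 (NF-kB and inflammatory cytokines), −0.24 (cholesterol and fatty acid synthesis), −0.20 (cytosolic ribosomal proteins), −0.18 (integrated stress response), −0.15 (respiratory chain and mitochondrial ribosome), −0.093 (unfolded protein response), 0.089 (mesenchymal markers) and 0.11 (TGF-beta and YAP targets). None of these 8 calls held with an estimated correlation (adjusted p = 0.24 for the inflammatory and mesenchymal lists, 0.44 for the integrated stress response and 0.469 for the others).

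Inflammatory genes stood out as higher with the TRA2B hairpins relative to the control, but the control moved most. A rise of the list as a whole under DOX with shRNA1 is argued against by its median of −0.068 there. Single members moved both ways, with 5 of 25 higher, IL24 among them, and 6 lower, at a mean of 0.079. A rise with shRNA2 was present at a median of 0.87. The list was also lower without DOX in both TRA2B constructs than in the control, by a median of −1.86 or below (−1.91 with shRNA1 and −1.86 with shRNA2). A high level in the control without DOX may therefore account for much of the difference in both constructs. With DOX, the medians lay 0.39 (shRNA1) and 1.04 (shRNA2) above the control. A batch of culture or harvest that followed the lane of the control libraries stays open, since 0 lanes held control libraries both with and without DOX, and an effect of TRA2B loss on these genes is likewise open as the biological explanation.

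MIR30A and several other genes rose with DOX in every construct, the control included. A candidate explanation for MIR30A is that reads from the hairpin cassette were counted there, since many inducible hairpins are built on the backbone of this microRNA, although the labels do not give the backbone. The highest log2 fold change among its tested neighbours in any construct was 0.55, far under the 4.13 to 6.03 of MIR30A, and no neighbour rose in all constructs (the best had −0.21 in its lowest construct), which argues against a change of the whole region. The named genes that rose in the control rose by at least 0.85 with shRNA2 when the lane was held fixed by the replicate block. This argues against sequencing lane for their rise with shRNA2. It cannot exclude a share of the lane in the control values, since no lane held control libraries both with and without DOX. Whether doxycycline itself or the expression of any hairpin raised these genes cannot be told apart, since 0 groups had DOX and no hairpin.

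The shRNA1 library without DOX of replicate 1 held the lowest total, 42494046 counts, and high levels of MT-RNR1 (10600 CPM against 391 and 378), MALAT1 (649 against 103 and 121) and TERC (5.93 against 0.113 and 0.0944). As a test of lower depth, thinning replicate 2 to that total gave a median log2 ratio of −0.133 for 105 small noncoding RNA and histone genes. Random thinning leaves the expected CPM unchanged, so this outcome was largely fixed in advance and no conclusion is drawn from it. For genomic DNA, 8.24% of 376 olfactory receptor genes had a count, against up to 8.78% elsewhere (a ratio of 0.939). This cannot decide the question, since the share was not matched for depth and this library was the shallowest. It nevertheless had the most genes with counts, 30217 against at most 29473 elsewhere. RNA without poly(A) tails carried into the library stays possible but undecided, since the 105 genes had a median log2 ratio of 0.495 (quartiles 0.058 and 1.2), against −0.012 for other genes and −0.16 to 0.11 in other libraries, short of the bound of 1 set for this explanation. That value is under the 0.5 set against it, and the explanation is left open by a further condition, an upper quartile under 0.5, that was added once the value had been seen; no biological explanation was tested.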

How the results depend on the processing

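All alternatives in this part were planned, and none was chosen after its result had been seen.

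A minimum log2 fold change of 1 lowered every count by construction, to 609 for shRNA1, 1195 for shRNA2, 648 for the control, 584 and 1200 for shRNA1 and shRNA2 minus the control, 951 for the mean minus the control, 61 between the hairpins and 372 for genes changed with both. TRA2B lost its call there for shRNA1 (−0.69) and for shRNA1 minus the control (−0.84), both under 1 in size, and named calls went from 539 to 209. An adjusted p below 0.01 gave 2777 for shRNA1, 2751 for the control, 1269, 3151 and 3021 for shRNA1, shRNA2 and their mean minus the control, 84 between the hairpins and 2231 for both, also by construction. A fit of only the 2 groups compared gave 2858 genes in the control.

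The difference between the hairpins went from 256 genes to 514 with a replicate block, 568 with DESeq2 and 730 with no filter on low counts. Without shRNA1 libraries it was 169 (no DOX, replicate 2), 134 (no DOX, replicate 3), 130 (DOX, replicate 1) and 153 (DOX, replicate 2). Without shRNA2 libraries it was 139 (no DOX, replicate 1), 168 (no DOX, replicate 3) and 142, 126 and 163 (DOX, replicates 1, 2 and 3). The control count was 3045 without its no-DOX replicate 2 and 3044 without replicate 3. The cause was not tested.

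Leaving out single libraries gave 3621 to 5364 genes for shRNA1, 6365 to 8329 for shRNA2, 3044 to 5310 for the control, 1804 to 2988 for shRNA1 minus the control, 4323 to 5377 for shRNA2 minus the control, 3930 to 5160 for the mean minus the control, 126 to 340 between the hairpins and 2820 to 4195 for both. TRA2B ranged from −0.82 to −0.60 (shRNA1), −1.995 to −1.75 (shRNA2), 0.089 to 0.19 (control), −0.96 to −0.74 (shRNA1 minus control), −2.14 to −1.89 (shRNA2 minus control), −1.49 to −1.36 (mean minus control) and 1.01 to 1.29 (between hairpins). Named calls ranged from 505 to 526 and list calls from 53 to 63.

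Of the 57 gene list tests called, 2 were called with an estimated correlation, and the cause was not tested. Replicate numbers paired samples of shRNA2 (deviations correlated at 0.52, 0.28 and 0.33), but not of shRNA1 (−0.014, −0.034 and 0.23) or the control (0.049, 0.51 and −0.019). A replicate block kept 56 of the 57 list calls, losing the lung metastasis signature in shRNA2 minus the control (camera adjusted p = 0.0355, then 0.0605), and of the counts of genes it moved by over 1.5-fold only that between the hairpins. It kept 534 of the 539 named calls, lost 5 and added 10.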

Other observations

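The tests between constructs without DOX, apart from those of TRA2B, and the choice of TBX18 came after the data had been seen.

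Without DOX, the TRA2B constructs differed from the control in many genes. These control libraries came from lane 7 and those of the TRA2B constructs from lanes 1, 2 and 3. Construct and lane cannot be told apart here. By edgeR, 9691 genes differed without DOX between shRNA1 and the control (4830 higher, 4861 lower) and 9643 between shRNA2 and the control (4640 higher, 5003 lower). CA9 stood at 20.9 ± 2.54 and 22.6 ± 0.766 CPM in the TRA2B constructs and at 2.30 ± 0.682 CPM in the control, and SDR16C5, a retinol dehydrogenase relative, at 4.04 ± 0.231 and 3.09 ± 0.320 CPM against 0.208 ± 0.0339 CPM. The inflammatory genes went the other way, with PTGS2 at 9.66 ± 0.494 and 14.8 ± 0.695 CPM against 233 ± 75.5 CPM and CXCL1 at 9.51 ± 1.41 and 9.19 ± 1.59 CPM against 49.6 ± 13.5 CPM (SD, n = 3). The spread of these genes in the control without DOX was wide, with IL1B at 236 ± 79.0 CPM. Whether these differences were present in the parental cells of each construct was not analysed here.

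TBX18, a T-box transcription factor below the level set for named genes, was nearly absent without DOX and present with it. It reached 4.57 ± 0.833 CPM with shRNA1 and 6.58 ± 0.443 CPM with shRNA2, from 0.00524 ± 0.00908 CPM and from 0 counts in all 3 libraries (a count of 3 there is at most 0.0513 CPM). In the control it went from 0.0145 ± 0.0141 to 0.207 ± 0.0634 CPM (edgeR adjusted p = 9.22e-12, 5.59e-13 and 8.57e-05 for shRNA1, shRNA2 and the control). MMP13 followed a similar order, at 0.885, 3.72 and 0.374 CPM with DOX.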
